A study of Mus musculus with 6 samples.

How the data were processed

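RNA was sequenced from aortae of wild-type and Cnn1 knockout mice, 3 libraries each. Per the labels' protocols, frozen aortae were pulverized in TRIzol and total RNA was made into libraries with a stranded total RNA kit. The submitters' processing notes name Trimmomatic 0.36, STAR 2.6.0c, Subread 1.6.1 with featureCounts and the genome build GRCm38. The settings of each tool, the strand setting and the annotation release are not given in the sources used here. The authors deposited read counts per gene in a pair of tables, one with uniquely mapped reads only and one with multi-mapping reads allowed, per the file headers and titles of the tables. They also deposited a normalized signal for each table. Every column of that deposited signal equalled the matching counts divided by 1 factor per library, which was the median-of-ratios size factor of DESeq2 (largest relative difference 5.2e-15), so it was not tested separately.

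The tables list 53735 genes, of which 30822 had a unique count and 35124 a count with multi-mapping reads allowed, 4302 of them only in the latter. Unique counts totalled 25926198, 30302720 and 33314888 in the wild-type libraries Wt_217, Wt_350 and Wt_357 and 35438701, 29739027 and 30665498 in the KO libraries Mut_358, Mut_359 and Mut_365. With multi-mapping reads the totals ran from 31171266 to 42036329. Reads shared between near-identical genes are lost in the unique table and can be counted more than once in the other, and 7 of the 13 mitochondrially encoded genes had enough unique counts to be tested. A stranded kit does not by itself show that counting used strand, so overlapping antisense genes are uncertain. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 14.2 to 70.3). Gene positions came from GENCODE M21 on GRCm38, which may not be the release the authors used, and 28523 genes were placed by symbol and 256 by an older symbol.

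Unique counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (a minimum count of 10 and a total of 15), libraries were scaled with TMM, and the quasi-likelihood F test compared KO with wild-type, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 over 17653 genes. Fold changes are log2 of KO over wild-type. Standard errors were derived from the fold change and its F statistic, and 95% intervals had a median half-width of 0.27. The common biological coefficient of variation was 17.0%. CPM values use TMM-scaled library sizes.

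Before the data were examined, 26 gene lists, the tests and the rule for naming genes were fixed. The vascular tone list as tested also holds the contractile gene Ppp1r14a, which the written plan did not name in that list. Lists with at least 3 tested members (25) were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with camera at an estimated correlation and fry as companions. List levels per library are medians of log2(CPM + 0.1). The lists cover contractile, paralog, vascular tone, SRF regulator, matrix, immediate-early, cell-cycle, p53, interferon, inflammation, oxidative phosphorylation, clock, ribosomal and mitochondrially encoded genes, and markers of endothelium, fibroblasts, macrophages, lymphocytes, white and brown fat, skeletal and cardiac muscle, Schwann cells and neurons, red cells, epithelium, and lymph node, thymus and cartilage. The genes named are Cnn1 and its paralogs, up to 15 called genes per direction, or the 8 with the smallest p where fewer than 5 were called, with a mean of at least 1 CPM and groups that do not overlap, leaving out symbols of predicted genes, in each list up to 4 called members, or else the 2 with the smallest p and the most abundant, and called genes within 5 Mb of Cnn1. Smtn, Ldb3, Des, Synm, Sorbs1, Acta2, Myl6, Col18a1, Eln, the Schwann cell genes, Hspa5, Elavl3 and the flanking genes were named after their values were seen. Neighbours of Cnn1 were compared with other genes by a two-sided Fisher exact test.

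The test was tried on simulated counts with the real means, dispersions and library sizes, with 200 genes changed. Of 17447 simulated genes tested for the KO against wild-type comparison, it recovered 19.4% of those changed 1.5-fold, 59.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 17 false calls among 133. Over 10 further draws 6.6% of edgeR calls and 22.5% of DESeq2 calls were false. The simulated data were more even than the real ones, with a median of 7.16 prior degrees of freedom in edgeR against 3.04, and recovery at the real spread was not measured. With no gene changed, 0 were called, and camera found the list that had been shifted and called 0 others. Every member of that list had been raised 2-fold, and smaller shifts of a list were not tried. The simulated genes varied independently, whereas the estimated correlation in the real lists was 0.622 for contractile and 0.972 for erythroid genes. The simulation therefore could not show how often camera calls lists of correlated genes falsely.

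The alternatives were the multi-mapping counts, DESeq2 1.42.0, limma-voom, RLE size factors, library totals, no filter, a filter at a mean of 1 CPM, a robust dispersion, Xist level as a covariate, stricter and looser thresholds, windows of 2 and 10 Mb, and leaving out each library in turn. A further 3 were added after seeing the data: leaving out Mut_358 and Mut_365 together, and covariates for neuronal and skeletal muscle markers. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.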

Results

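Total RNA from mouse aorta was sequenced in 6 libraries, 3 from wild-type mice (Wt_217, Wt_350 and Wt_357) and 3 from Cnn1 knockout mice (KO; Mut_358, Mut_359 and Mut_365). Cnn1 encodes calponin 1, an actin-binding protein of differentiated smooth muscle. The series title poses the question of how loss of Cnn1 alters the transcriptome of aortic smooth muscle. The libraries came from aortic tissue, which besides smooth muscle holds endothelium, adventitial fibroblasts and immune cells and can carry nerve and fat. Between 25926198 and 35438701 uniquely mapped reads per library were assigned to genes, with a mean of 29850000 ± 3720000 in wild-type (SD, n = 3) and 31950000 ± 3060000 in KO (SD, n = 3). Each library carries its own number in the labels, which do not state that each number is a separate animal, so the p-values measure the spread between these libraries.

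Cnn1 was almost absent from the KO libraries. Its level, in counts-per-million (CPM), was 844.7, 688.2 and 614.9 CPM in Wt_217, Wt_350 and Wt_357, and 8.86, 13.5 and 7.61 CPM in Mut_358, Mut_359 and Mut_365. The KO mean of 9.98 ± 3.09 CPM (SD, n = 3) was 1.39% of the wild-type mean of 716 ± 117 CPM (SD, n = 3), a 71.8-fold difference. The log2 fold change was -6.17 (SE 0.27) with an adjusted p of 0.0012 by the edgeR quasi-likelihood test. The Cnn1 level thus matched the genotype label in all 6 libraries. Cnn1 (ENSMUSG00000001349.5) lies on the plus strand of chromosome 9, from 22099216 to 22109630 in GRCm38, and no other gene of GENCODE M21 overlaps it. The KO libraries still held 318, 394 and 231 unique counts for the gene, and the gene-level counts do not show which exons these reads came from.

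**Figure D1:**
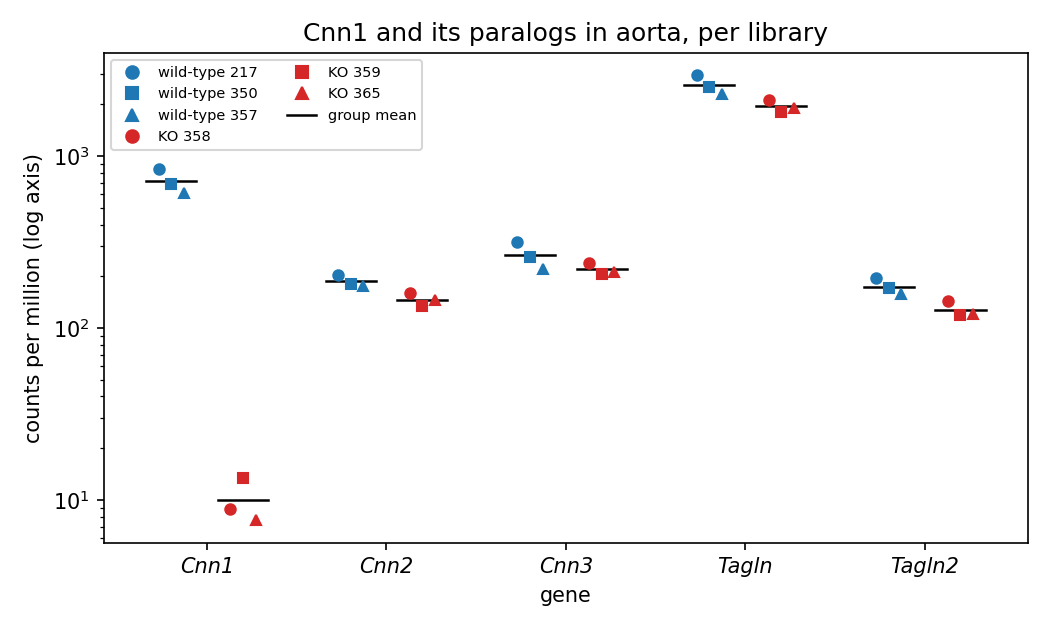
Level in CPM (log axis) of Cnn1 and 4 related genes in each library, with wild-type in blue, KO in red and black lines for the group means (n = 3 each). Cnn1 lies between 614.9 and 844.7 CPM in wild-type and between 7.61 and 13.5 CPM in KO, whereas the related genes differ far less.

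Among 17653 genes tested, Cnn1 was the only gene that changed at an adjusted p under 0.05 by edgeR, and 0 genes rose. At an unadjusted p under 0.05 there were 890 genes higher and 788 lower. limma-voom also called 1 gene lower and 0 higher, whereas DESeq2 on the same counts called 392 genes, 316 higher and 76 lower. Without Mut_359, edgeR called 412 genes, 407 higher and 5 lower, the latter being Cnn1, Adamts8, Wdr95, Hspa5 and Wisp2. Many of the higher ones were neuronal genes with high levels in Mut_358 and Mut_365 only. Snap25, Tubb3 and Stmn2 measured 28.36, 37.14 and 23.88 CPM in Mut_358 but 1.61, 1.33 and 3.63 in Mut_359. DESeq2 also called these genes higher. By edgeR on all libraries the next smallest adjusted p was 0.149, for Adamts8, a secreted metalloprotease, at 80.7 ± 3.89 CPM in wild-type (SD, n = 3) and a log2 fold change of -0.86 (SE 0.08). The other genes with the smallest p on the lower side were Wdr95 (log2 fold change -0.60), Wisp2 (-0.49), Pamr1 (-0.51), Fam118a (-0.33), Cbr2 (-0.39) and Tspan9 (-0.37). On the higher side they were Abca7 (0.41), Adcyap1r1 (1.13), Nabp1 (0.80), Arhgef28 (0.40), Mir6236 (0.72), Ptprr (1.63), Nmnat2 (1.02) and Syp (1.55), of which Syp encodes the synaptic vesicle protein synaptophysin. All of these had an adjusted p of 0.37 by edgeR, with the 3 KO libraries on one side of the 3 wild-type libraries. Such separation was seen in 2675 genes, or 15.2% of those tested, where chance alone gives 10%. Among genes with a mean of at least 1 CPM the median absolute log2 fold change was 0.10, and 93.9% lay under 0.5.

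Library Mut_359 stood apart in its sex-linked transcripts, with Xist at 1466.9 CPM and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y at 0. In the other 5 libraries Xist lay under 1 CPM and Ddx3y between 136 and 172 CPM. The KO group thus joined 1 library with a female pattern to 2 with a male pattern, while the wild-type libraries had a male pattern. The same library also had fewer neuronal transcripts than the rest of its group: the median level of 19 noradrenergic markers was 26.3 CPM in Mut_358, 1.27 in Mut_359 and 17.9 in Mut_365, against at most 0.95 in wild-type. With the Xist level as a covariate edgeR called 202 genes, and with the neuronal marker level as a covariate it called 1. Xist was high only in Mut_359, so its covariate comes close to leaving that library out. The neuronal markers were high only in Mut_358 and Mut_365, so the other covariate leaves the KO effect resting largely on Mut_359.

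Smooth muscle contractile genes lay lower in KO as a group, by a small margin. Of 27 members tested, 23 were lower, the median log2 fold change was -0.29, and the camera set test gave an adjusted p of 2.0e-07. With an estimated correlation between members the adjusted p was 0.8. Without Wt_217, which had the highest level of these genes, 21 were lower and the median was -0.15 (adjusted p 3.4e-04). Acta2, the smooth muscle actin, measured 8769 ± 942 CPM in wild-type (SD, n = 3) and 6224 ± 706 CPM in KO (SD, n = 3), a log2 fold change of -0.49. Csrp1 had -0.43, Ppp1r14a -0.41 and Myl6, a myosin light chain, -0.29. Flna, the actin cross-linker filamin A and the most abundant member, had -0.32 (SE 0.13). Des, at 0.31 (SE 0.45), Synm, Sorbs1 and Ldb3, at 0.05 (SE 0.09), lay higher by less than their errors, and Smtn (-0.03, SE 0.08) and Myocd, the coactivator that drives contractile genes (-0.02, SE 0.09), lower by less than theirs. Over all genes tested 0 members passed by edgeR and 0 by limma-voom, 11 lay lower at an unadjusted p under 0.05, and DESeq2 called 5 lower. Adjusted over the list alone 4 passed, namely Csrp1, Ppp1r14a, Acta2 and Myl6, but 0 did without Wt_217, Wt_350, Mut_359 or Mut_365 or with multi-mapping reads counted, against 7 without Wt_357 and 11 without Mut_358. Markers of macrophages, fibroblasts and endothelium had median log2 fold changes of 0.32, 0.15 and 0.12, or 0.16, 0.03 and 0 without Mut_359.

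With all 6 libraries and no covariate, no close relative of Cnn1 passed the edgeR test over all genes. Cnn2 had a log2 fold change of -0.35 (SE 0.09), Tagln -0.41 (SE 0.12), Tagln2 -0.45 (SE 0.11) and Cnn3 -0.27 (SE 0.14), with 0 past the threshold over all genes by edgeR or limma-voom. Tagln3, a neuronal transgelin present at 0.58 CPM in wild-type, had 1.97 (SE 0.45), and edgeR called it higher without Mut_359 (2.33, adjusted p 0.0072) and with the Xist covariate (2.34, 0.013). At an unadjusted p under 0.05 there were 3 members lower and 1 higher, which were also the numbers that DESeq2 called. Adjusted over the list alone, 4 of the 5 members passed, and camera gave an adjusted p of 0.027 toward lower levels, or 0.8 with an estimated correlation. The mean log2 fold change of this list was 0.10, of the opposite sign to its median of -0.35, because of Tagln3. The camera call was lost in 7 of 11 refits, among them those without Wt_217 (adjusted p 0.11), Mut_359 (0.36) or Mut_365 (0.088) and with the Xist (0.33), neuronal (0.092) or skeletal muscle (0.055) covariate. Genes of vascular tone and calcium handling were lower in 19 of 24 cases, with a median of -0.10 and a camera adjusted p of 0.022, or 0.8 with an estimated correlation. The member with the smallest p, Ppp1r14a (-0.41), is also in the contractile list. Kcnmb1, a subunit of the large-conductance potassium channel, had -0.42 (SE 0.12), and Rgs5, the most abundant member, had -0.09 (SE 0.17). By edgeR and limma-voom 0 members passed over all genes, and 0 passed by edgeR when adjusted over the list alone, with 4 lower and 1 higher at an unadjusted p under 0.05 and 1 called lower by DESeq2. The camera call of the vascular tone list was lost without Wt_217 (adjusted p 0.47, with 12 higher, 12 lower and a median of -0.01), Mut_359 (0.31, median -0.05) or Mut_365 (0.088), and with the Xist (0.31) or skeletal muscle (0.067) covariate. The SRF, MRTF and KLF regulators were not called (camera adjusted p 0.68), with Klf4 at 0.31 (SE 0.10) and Srf at -0.20 (SE 0.10).

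Extracellular matrix genes lay lower in KO by a very small margin. Of 37 tested, 21 were lower and 16 higher, with a median of -0.06, a camera adjusted p of 0.022 and an adjusted p of 0.8 with an estimated correlation. Without Wt_217 there were 30 lower and 7 higher, with a median of -0.12 (adjusted p 5.4e-05), and without Mut_359 26 lower and 11 higher. Comp (log2 fold change -0.62), Tnc (-0.34) and Col18a1 (-0.44) passed when adjusted over the list alone. That count of 3 became 0 without Wt_217, Wt_357, Mut_359 or Mut_365, 1 without Wt_350 and 5 without Mut_358. Over all genes 0 passed by edgeR and 0 by limma-voom, with 8 lower at an unadjusted p under 0.05 and 4 called lower by DESeq2. Col3a1, a fibrillar collagen and the most abundant member, had 0.13 (SE 0.22), and Eln, elastin, had -0.36 (SE 0.22). The camera call was lost without Wt_350 (adjusted p 0.13), Wt_357 (0.15) or Mut_365 (0.1), with medians of -0.03, -0.03 and -0.01, and with the skeletal muscle covariate (0.055), and without Mut_358 the median was -0.03.

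Transcripts encoded by the mitochondrial genome lay higher in KO. All 7 members tested were higher, with a median log2 fold change of 0.41 and a camera adjusted p of 1.1e-06, or 0.8 with an estimated correlation. Adjusted over the list alone 6 passed. Over all genes 0 did by edgeR and 0 by limma-voom, whereas 6 lay higher at an unadjusted p under 0.05 and DESeq2 called 6 higher. mt-Nd4 had 0.45 (SE 0.09), mt-Nd2 0.47 (SE 0.11) and mt-Co1, the most abundant, 0.36 (SE 0.11). Protein-coding mitochondrial genes took 1.77 ± 0.03% of counts in wild-type (SD, n = 3) and 2.31 ± 0.22% in KO (SD, n = 3). Mitochondrial ribosomal RNA took 4.63 ± 0.39% and 6.07 ± 0.99% (SD, n = 3 each), although Mut_358, at 4.93%, lay below Wt_217 at 4.97%. Nuclear genes of oxidative phosphorylation and fatty acid oxidation were higher in 28 of 30 cases, with a smaller median of 0.16 and a camera adjusted p of 0.0085, or 0.8 with an estimated correlation. Ndufs1 had 0.23 (SE 0.13), Atp5b 0.20 (SE 0.16) and Cpt1b 0.42 (SE 0.22). That call was lost without Wt_217 (adjusted p 0.96, with 21 of 30 higher and a median of 0.02), Mut_359 (0.47, median 0.07) or Mut_365 (0.088), and with the Xist (0.33) or skeletal muscle (0.055) covariate, whereas the median was 0.26 without Wt_350 and 0.28 without Mut_358. The level of this list was lowest in Wt_217 and highest in Mut_359, as were those of the white and brown adipocyte lists. All 28 ribosomal protein genes were lower by a median of only -0.10, with a camera adjusted p of 3.1e-05, or 0.8 with an estimated correlation. Without Mut_358 the median was -0.05, with 4 of 28 higher (adjusted p 0.019). Rps25 had -0.18, Rpl37 -0.17 and Rpl4 -0.05. The ribosomal list turned direction and lost its call with the neuronal marker level as a covariate (adjusted p 0.74). With Mut_359 as the single KO library left, 7 of 28 were higher, the median was -0.03 and the adjusted p 0.14. In these nuclear lists 0 genes passed by edgeR, limma-voom or DESeq2 over all genes, and at an unadjusted p under 0.05 there were 0 of oxidative phosphorylation and 3 ribosomal genes, all lower.

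Neuronal transcripts were abundant in 2 of the 3 KO libraries. Th, the rate-limiting enzyme of catecholamine synthesis, measured 36.95 CPM in Mut_358, 2.16 in Mut_359 and 23.33 in Mut_365, against 0, 0.03 and 0.71 in Wt_217, Wt_350 and Wt_357. Dbh, which makes noradrenaline, measured 75.76, 2.6 and 41.61 CPM in the KO libraries and at most 1.39 in wild-type. Snap25 followed the same pattern, with 28.36, 1.61 and 18.65 CPM. The list of Schwann cell and neuron markers had 12 of 15 members higher, a median log2 fold change of 0.59 and a camera adjusted p of 1.1e-04, or 0.8 with an estimated correlation. Adjusted over the list alone 7 passed, or 0 without Wt_217. Over all genes 0 did by edgeR and 0 by limma-voom, whereas 7 lay higher at an unadjusted p under 0.05, DESeq2 called 6 higher, and edgeR called 6 without Mut_359 and 6 with the Xist covariate. Without Mut_365 the median was 0.34. With Mut_359 as the single KO library left, the median was 0.34 and the adjusted p 0.11, and with the neuronal covariate, built from members of this list, they were -0.31 and 0.15. The Schwann cell genes in the list went both ways, with Cdh19 at 0.59 (SE 0.17), Sox10 at 0.59 (SE 0.34), Plp1 at 0.45 (SE 0.21), Mbp at 0.30 (SE 0.25), S100b at 0.21 (SE 0.15), Mal at 0.12 (SE 0.27), Mpz at -0.04 (SE 0.57), Prx at -0.08 (SE 0.13) and Ncmap at -0.68 (SE 0.31).

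**Figure D2:**
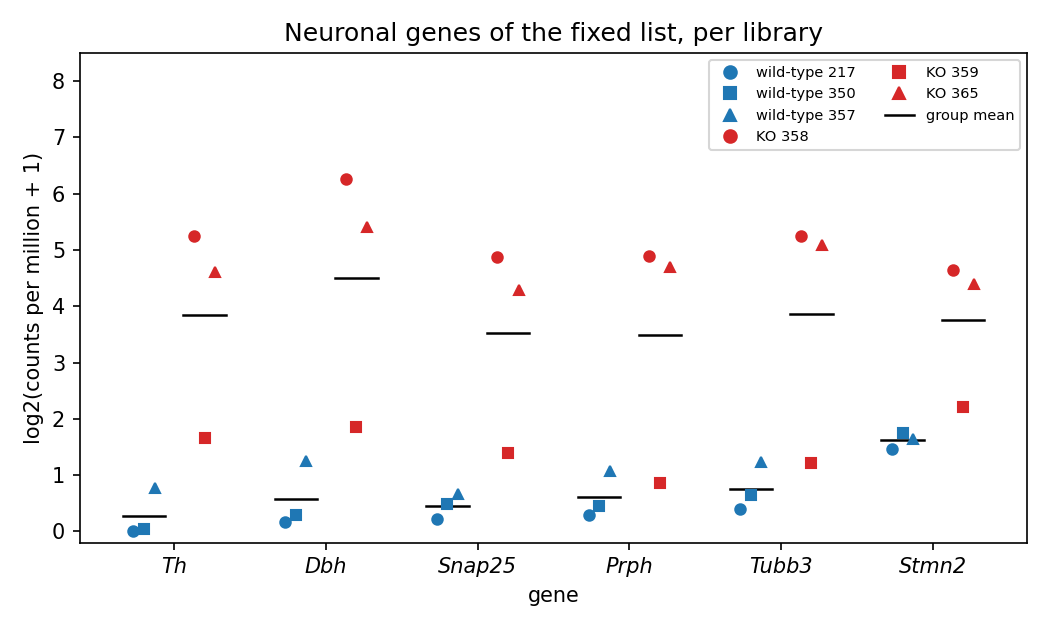
Level of 6 neuronal genes in each library as log2(CPM + 1), with wild-type in blue, KO in red and black lines for the group means (n = 3 each). Mut_358 and Mut_365 lie well above the wild-type libraries, with Th at 36.95 and 23.33 CPM, whereas Mut_359 lies close to them at 2.16 CPM.

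Markers of other tissues also varied between libraries. Skeletal muscle markers were higher in 17 of 17 cases with a median of 2.21, but the camera adjusted p was 0.1, or 0.048 with multi-mapping reads counted and 0.045 with the neuronal covariate. Mut_365 had the highest level of these markers and Mut_358 the lowest of the 6 libraries. Without Mut_358 the adjusted p was 1.2e-11 and 16 members passed when adjusted over the list alone, and without Mut_365 it was 0.65, with 15 of 17 still higher and a median of 0.87. Actn3, a fast-fibre actinin, had a log2 fold change of 2.18 (SE 0.91), Eno3 1.53 (SE 0.69) and Myh1 2.42 (SE 1.57). Cardiac muscle markers had a camera adjusted p of 0.47, with Myl4 at -1.42 (SE 0.76), Mybpc3 at -2.41 (SE 1.36) and Ryr2 at -0.09 (SE 0.11). Myl4 and Mybpc3 were highest in Wt_357, at 39.95 and 12.69 CPM. Without that library 11 of 12 cardiac members were higher, with a median of 1 (adjusted p 0.32). White adipocyte markers (adjusted p 0.31) included Slc2a4 at 0.46 (SE 0.22), Lipe at 0.24 (SE 0.18) and Car3 at -0.14 (SE 0.20), and were called higher without Wt_350 (0.017) or Mut_358 (0.037). Brown adipocyte markers (0.2) included Ucp1 at 0.51 (SE 0.45), Fabp3 at 0.81 (SE 0.50) and Ckmt1 at 2.88 (SE 1.23), and were called higher without Wt_350 (0.049) or Mut_358 (0.025). In Mut_358, Mut_359 and Mut_365, Fabp3 measured 6.69, 15.64 and 32.68 CPM and Ckmt1 2.09, 0.14 and 1.85 CPM. Epithelial and mesothelial markers (0.86) had a median of -0.12 although camera pointed to higher levels, with Wt1 at -0.64 (SE 0.52) and Krt18 at -0.12 (SE 0.17), and were called higher without Wt_357 (3.5e-04). Only 2 genes of the lymph node, thymus stroma and cartilage list were tested, Sox9 at 0.32 (SE 0.17) and Ccl19 at 0.11 (SE 0.18), too few for a set test. Erythroid markers were lower in 5 of 5 cases, with a median of -0.76 and a camera adjusted p of 0.0026, or 0.8 with an estimated correlation. They included the globins Hbb-bt at -0.85 (SE 0.29) and Hbb-bs at -0.53 (SE 0.21). Without Wt_350, which had the highest erythroid level, the median was -0.37 (adjusted p 0.022). Adjusted over the list alone 0 erythroid genes passed, or 5 without Mut_358. In these marker lists 0 genes passed over all genes by edgeR, limma-voom or DESeq2. At an unadjusted p under 0.05 there were 1 skeletal muscle gene higher and 2 erythroid genes lower.

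Macrophage, interferon and endothelial lists lay slightly higher in KO, but none of the 3 was called without Mut_359 or without Wt_217. Macrophage markers were higher in 19 of 19 cases with a median of 0.32 and a camera adjusted p of 6.4e-04, or 0.8 with an estimated correlation, and Fcer1g (0.48), Lyve1 (0.41) and Lyz2 (0.25) were among them. Interferon-stimulated genes were higher in 22 of 24 cases with a median of 0.23 and an adjusted p of 0.0026, or 0.8 with an estimated correlation. Ifit1 had 0.93 (SE 0.31), Ifit3 0.84 (SE 0.29) and Ddx58 0.05 (SE 0.10). Endothelial markers were higher in 16 of 18 cases with a median of 0.12 and an adjusted p of 0.027, or 0.8 with an estimated correlation. Emcn had 0.33 (SE 0.09), Cdh5 0.28 (SE 0.12) and Vwf 0.08 (SE 0.31). Of these 3 lists 0 genes passed over all genes by edgeR, limma-voom or DESeq2, and at an unadjusted p under 0.05 there were 2 macrophage, 3 interferon and 1 endothelial genes, all higher. Adjusted over the list alone 0 passed, whereas without Mut_358 there were 3 interferon and 3 endothelial genes, and without Mut_365 there was 1 endothelial gene. Without Mut_359 the camera adjusted p was 0.14 for macrophage, 0.36 for interferon and 0.97 for endothelial genes, of which 8 were then higher and 10 lower with a median of 0. The macrophage median was 0.09 without Wt_217 (14 of 19 higher), 0.16 without Mut_359 and 0.58 without Wt_350. The interferon median was 0.10 without Wt_217 (18 of 24 higher) and 0.12 without Mut_359, and the endothelial median 0.19 without Wt_350 and 0.22 without Mut_365. With the Xist covariate the adjusted p was 0.059 for macrophage, 0.27 for interferon and 0.97 for endothelial genes. Without Wt_217 it was 0.29, 0.42 and 0.15, and for endothelial genes it was also 0.15 without Wt_357. Adventitial fibroblast markers were not called (adjusted p 0.1), with Mfap5 at -0.32 (SE 0.13) and Dcn at 0.21 (SE 0.12), but were called higher without Wt_357 (0.005) or Mut_358 (0.025). Lymphocyte markers were not called (0.33), with Il7r at 1.55 (SE 0.43), Igkc at -0.80 (SE 0.37) and Ighm at -0.25 (SE 0.22).

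**Figure D3:**
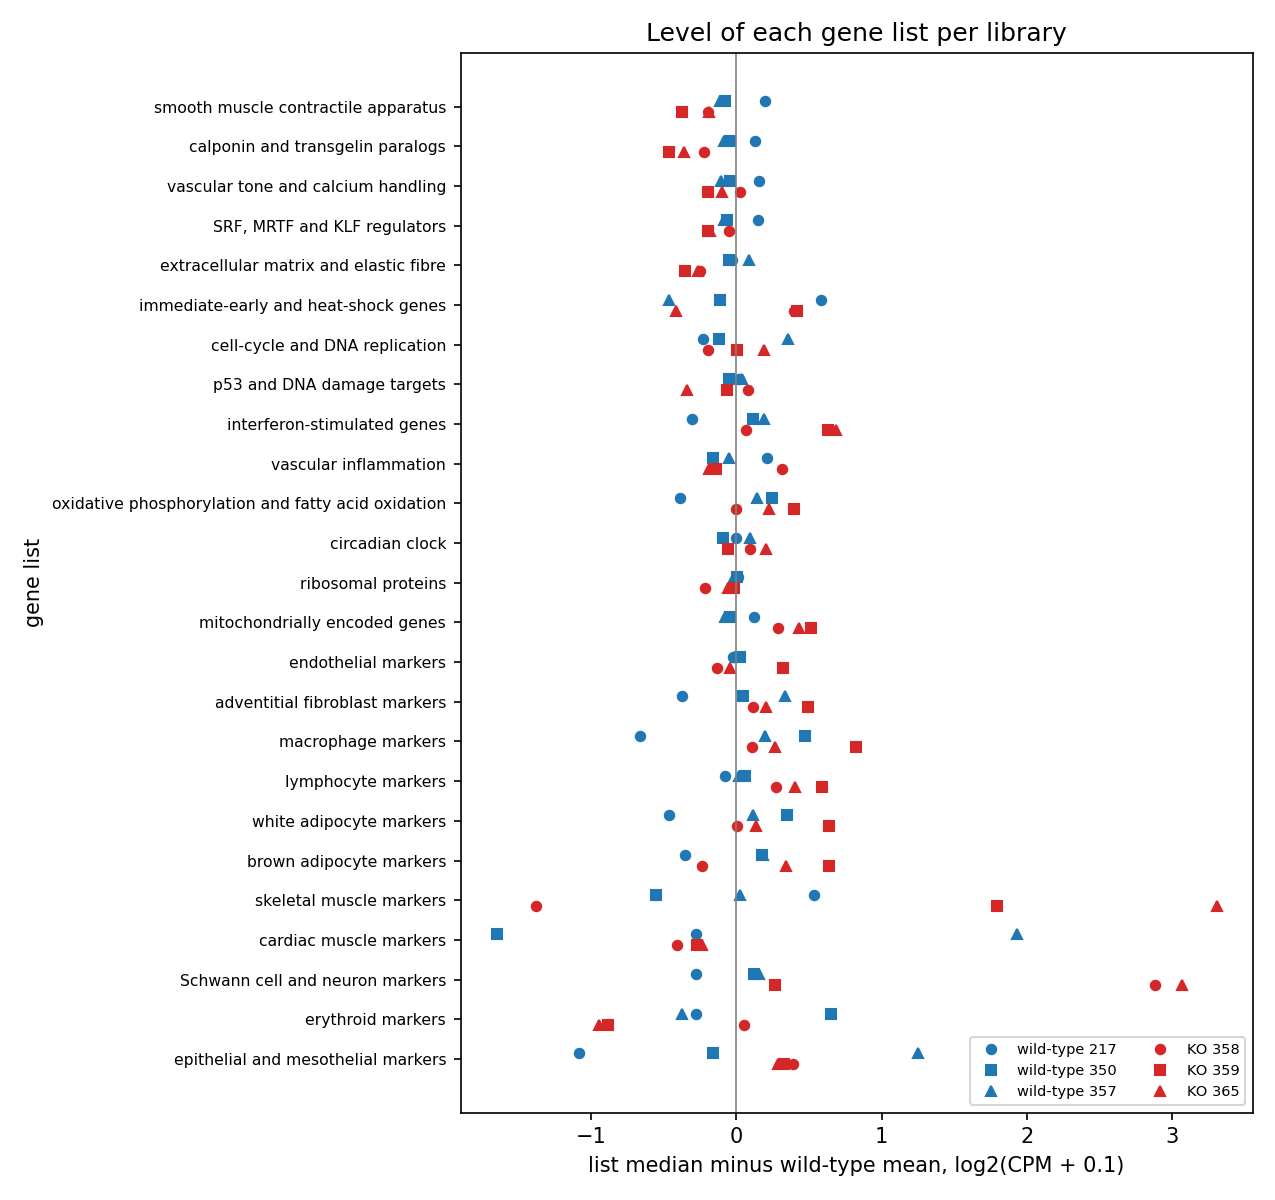
Median level of each of the 25 gene lists in each library, as log2(CPM + 0.1) relative to the mean of the wild-type libraries, with wild-type in blue and KO in red. The mitochondrially encoded list lies higher in all 3 KO libraries, the neuronal list in Mut_358 and Mut_365, and the skeletal muscle list highest in Mut_365.

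The remaining programs were not called by camera. Immediate-early and heat-shock genes had an adjusted p of 0.47, with Ier2 at -0.42 (SE 0.17), Egr1 at -0.49 (SE 0.27) and Klf6 at 0.14 (SE 0.26), and without Wt_217 they were called in the opposite direction (adjusted p 0.048). Cell-cycle genes had 0.25, with Ccne1 at 0.79 (SE 0.28) and Mcm6 at -0.16 (SE 0.09), and were called higher without Wt_357 (4.8e-04) or Mut_358 (0.019). The p53 target list had 0.7, with Ddit4l at 1.34 (SE 0.62), Tnfrsf10b at -0.27 (SE 0.14) and Trp53inp1 at 0.26 (SE 0.32), and camera pointed lower where the median was 0.01. Ddit4l measured 1.56, 4.21 and 10.35 CPM in Mut_358, Mut_359 and Mut_365. The vascular inflammation list had 0.36, with Cxcl12 at 0.23 (SE 0.11) and Lcn2 at 0.62 (SE 0.31). Circadian clock genes had 0.36, with Ciart at 1.13 (SE 0.44), Arntl at -0.56 (SE 0.22) and Clock at -0.14 (SE 0.08).

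Of 79 genes tested within 5 Mb, edgeR called 0 besides Cnn1, limma-voom called 0, and DESeq2 called 1, the neuronal gene Elavl3, which edgeR also called without Mut_359 (log2 fold change 4, adjusted p 0.011). At an unadjusted p under 0.05 there were 6, or 7.59%, against 10.4% of genes elsewhere (two-sided Fisher exact p = 0.58). The flanking genes Ecsit (log2 fold change 0.06, SE 0.11), Elof1 (-0.03, SE 0.09) and Acp5 (0.01, SE 0.23) differed by less than their errors.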

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

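The alternatives that left out Mut_358 and Mut_365 together or used the neuronal or skeletal muscle marker level as a covariate were chosen after seeing the data. Cnn1 stayed lower and past the threshold in all 18 refits, with log2 fold changes from -6.46 to -5.39. The count of 1 changed gene (0 higher, 1 lower) was the same with multi-mapping counts, RLE size factors, library totals, a mean of 1 CPM, a robust dispersion, limma-voom, both marker covariates, an adjusted p under 0.1 and an absolute log2 fold change of at least 1. DESeq2 called 392 genes (316 higher, 76 lower), the Xist covariate 202 (199 higher, 3 lower), no filter 2 (both lower, Cnn1 and Adamts8), and leaving out Mut_358 and Mut_365 gave 6 (1 higher, 5 lower: Xist, 4 Y-linked genes and Cnn1). That refit leaves 1 KO library, Mut_359, assumed to vary like the wild-type libraries, so it compares that library with them. In it camera no longer called paralog (adjusted p 0.078), matrix (0.13), ribosomal (0.14) and neuronal (0.11) genes, and called fibroblast (0.0072), brown adipocyte (0.0049), skeletal muscle (1.4e-06) and inflammation (0.048) genes higher. Leaving out each library in turn gave 1 to 412 genes, 0 to 407 higher and 1 to 5 lower, with 412 without Mut_359 and 1 without each of the others. All 202 genes called with the Xist covariate were among those 412, as were 245 of the 392 of DESeq2. Xist was high only in Mut_359, so that covariate comes close to leaving Mut_359 out. Otherwise the cause of the moved counts was not tested. Among simulated genes 22.5% of DESeq2 calls and 6.6% of edgeR calls were false. In simulated data, which were more even than the real ones, 19.4% of 1.5-fold changes were recovered. Adamts8 kept its direction in all 18 refits, with an adjusted p from 1.5e-12 (DESeq2) to 0.61 (without Mut_365).

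The 12 called gene lists became 0 with an estimated correlation, 0 by fry, 6 with the Xist covariate, and 6 to 17 on leaving out each library, with 7 without Wt_217 and 6 without Mut_359. In 11 refits at the preset correlation 3 lists kept their call throughout: contractile, mitochondrially encoded and erythroid genes. Of 89 named genes 17 reversed in at least 1 refit, none of them called, and camera's direction turned for 14 lists; the cause was not tested. With the neuronal covariate the log2 fold changes were 0.066 for Rgs5, 0.19 for Myocd, -0.22 for Trp53inp1, -0.027 for Ddx58, 0.25 for Arntl, 0.085 for Clock, -2.67 for Ckmt1 and 0.22 for Krt18. Without Mut_358 and Mut_365 they were 0.065 for Myocd, -0.063 for Trp53inp1, -0.40 for Ckmt1 and 0.13 for Krt18. Vwf had -0.27 with the Xist covariate, and Myh1 -1.48 with the skeletal muscle covariate and -0.29 with limma-voom. On leaving out each library the ranges were -0.24 to 0.12 for Rgs5, -0.092 to 0.049 for Myocd, -0.088 to 0.30 for Col3a1, -0.031 to 0.52 for Klf6, -0.24 to 0.51 for Trp53inp1, -0.003 to 0.16 for Ddx58, -0.076 to 0.001 for Rpl4, -0.25 to 0.34 for Vwf, -0.005 to 0.51 for Lyz2, -0.42 to 0.005 for Car3, -1.85 to 0.051 for Myl4, -3.18 to 0.82 for Mybpc3 and -0.25 to 0.021 for Krt18.

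Camera sets a list against the other genes, so its direction can turn while the members keep theirs, and the adjusted p-values of lists where it turned follow. With the neuronal covariate it was 0.29 for immediate-early, 0.74 for cell-cycle, 0.74 for p53, 0.15 for clock, 0.74 for ribosomal, 0.15 for neuronal and 0.68 for epithelial genes. Without Mut_358 and Mut_365 it was 0.7 for p53, 0.7 for clock and 0.84 for cardiac genes, of which 9 of 13 were still lower with a median of -1.41. Epithelial genes had 0.91 with multi-mapping counts and 0.95 with the Xist covariate. On leaving out each library it ranged from 0.42 to 0.97 for SRF regulators, 0.048 to 0.86 for immediate-early, 4.8e-04 to 0.91 for cell-cycle, 2.4e-05 to 0.96 for oxidative phosphorylation, 0.005 to 0.97 for fibroblast, 0.11 to 1 for lymphocyte, 0.025 to 0.97 for brown adipocyte, 1.2e-11 to 0.65 for skeletal muscle, 0.076 to 0.88 for cardiac and 3.5e-04 to 1 for epithelial genes.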

Other observations

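The tests on neuronal, smooth muscle share, skeletal muscle and nuclear copies of mitochondrial sequence were chosen after the result they measure was seen, and the first 3 were rewritten, bounds included, after first values had been seen. DESeq2 called 76 genes lower in KO, and those named here were also chosen after their values were seen, with no test of enrichment. Among them were the endoplasmic reticulum chaperones Hspa5 (log2 fold change -0.53, adjusted p 3.0e-04 by DESeq2), Calr (-0.31, 0.0071) and Hyou1 (-0.42, 0.031), and the cytoskeletal genes Actb (-0.40, 0.0069), Tmsb4x (-0.33, 0.043) and Lpp (-0.39, 0.031). Ptprz1, a receptor phosphatase, had -0.75 (0.0019), Itgb3, an integrin subunit, -0.49 (0.0062), and Nes, an intermediate filament, -0.51 (0.0097). By edgeR on all 6 libraries 0 of these passed, and without Mut_359 Hspa5 did. Among simulated genes 22.5% of DESeq2 calls were false.

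With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 gene by edgeR and the highest of the others 0, so that 1 of the 10 splits gave as many. By DESeq2 the real split gave 392 genes and the highest of the others 128, and 1 of the 10 gave as many. For gene lists the real split gave 12 and the highest of the others 15, and 4 of the 10 gave as many.

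Neuronal genes stood far above wild-type in Mut_358 and Mut_365. A candidate explanation is sympathetic ganglion tissue dissected with these aortae: of 19 detected noradrenergic markers, 84.2% (16) lay at least 4-fold above the highest wild-type library in both, against 0 of 2 chromaffin markers and 0 of 3 cholinergic markers, although Mut_365 alone had Vip at 10.02, Slc5a7 at 1.75 and Slc18a3 at 0.63 CPM, where wild-type had at most 0.09, 0.06 and 0. Among the most abundant were Slc6a2 (144.75 and 109.62 CPM) and Dbh (75.76 and 41.61 CPM), while Slc6a2 and Uchl1 were also present in every wild-type library, at 3.42 to 7.48 and 15.85 to 21.01 CPM. Among other neuron types 1 of 3 sensory markers (33.3%), Avil, was also at least 4-fold above wild-type in both, and 0 of 1 central neuron markers was. The noradrenergic markers include Th, Dbh, Stmn2, Prph, Tubb3 and Snap25 of the fixed list, whose height was itself the pattern. Some, such as Snap25, Tubb3 and Stmn2, are general neuronal genes. The share of 84.2% therefore does not by itself tell the neuron type. Th and Dbh, of catecholamine and noradrenaline synthesis, were each at least 4-fold above wild-type in both libraries. So were Ddc, Slc18a2, Slc6a2, Phox2a, Phox2b and Hand2, whereas Gata3, Uchl1 and Isl1 were not. These transcripts thus included noradrenergic ones, but they do not show which tissue they came from, and ganglion tissue stays open. An effect of the knockout on nerve cells stays open too: the median excess over wild-type was 25.6 CPM in Mut_358, 17.2 in Mut_365 and 0.57 in Mut_359, or 2.2% of the highest, but Mut_359 is a single library and the only one with a female pattern.

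The lower contractile genes were set against a technical trend and a change in cell makeup. Removing the trend of each library on transcript length and GC content left a contractile list median of -0.28, against -0.29 before. This argues against that trend as the cause for the contractile list. The paralog list went from an adjusted p of 0.028 to 0.074 as its median moved from -0.35 to -0.34. Its median absolute deviation was 0.14 and 0.12, so its call ended with almost the same fold. The ribosomal protein list moved from a median of -0.10 to -0.07 (camera adjusted p 1.3e-05 and 0.0013). Part of its small shift thus went with that trend. A smaller share of smooth muscle in the KO libraries stays open. Of 22 contractile members outside striated muscle and fat, 9.1% (Smtn and Myocd) had an interval wholly above the list median. Only 12 had intervals narrow enough to do so if unchanged, and Smtn and Myocd were 16.7% of those. Des, Ldb3, Synm, Sorbs1 and Fhl1 were left out, a choice made after the values were seen. All of these but Fhl1 lay higher in KO, so every member that rose was outside this count, which limits what it can show. The differences between endothelial, fibroblast and macrophage levels overlapped between the groups. Of 23 vascular tone genes outside the contractile list 8 had intervals wholly above the contractile list median. They were Ednra (0.22), Agtr1a (0.53), Kcnj8 (0.07), Cacna1c (0.02), Rock2 (-0.03), Abcc9 (-0.03), Prkg1 (-0.04) and Rhoa (-0.12). That list was not limited to genes of smooth muscle, so its count cannot decide for or against a smaller share. Lower expression within smooth muscle cells lacking Cnn1 was not separated from a smaller share by these data.

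Mitochondrially encoded transcripts lay higher in all 3 KO libraries. With the skeletal muscle marker level as a covariate the list median was 0.38, against 0.41 without it, which argues against skeletal muscle tissue as the whole cause. The rise of 0.41 in the 7 genes tested came from uniquely mapped reads. These leave out reads shared with nuclear copies of the mitochondrial genome, which argues against such reads as the cause in those genes. With multi-mapping reads counted all 13 genes were higher and the median was 0.42, with mt-Nd6 at only 0.10 (SE 0.07). Those counts include shared reads, so they cannot exclude them for the genes tested only there. Brown fat was not tested as a source. The brown adipocyte list level was highest in Mut_359 (5.72), as was that of the mitochondrially encoded list (10.75). In Mut_358, however, the brown adipocyte level (4.85) lay below Wt_350 (5.26) and Wt_357 (5.27). RNA quality and ribosomal RNA depletion that differed between the groups were not tested. An effect of the knockout stays open as a hypothesis.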
